A study of Mus musculus with 6 samples.

How the data were processed

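Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adaptors, in 6 libraries of mouse T follicular helper cells. The libraries came from 3 sorted populations, Tfh21, Tfh214 and Tfh4, of Stat6 wild-type (WT) and Stat6 knockout (KO) mice of strain C57BL/6, with 1 library for each genotype and population. Per the labels' protocols, each population was sorted from 10 mice per genotype, 50000 cells went into each library, tagmentation ran for 30 min at 37 °C, and reads of 75 bp were sequenced from both ends. The cells were untreated, and the tissue of origin was not given in the sources used here.

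The authors deposited 1 common list of 282898 peaks with a value in each of the 6 libraries. The values were CPM as deposited by the authors, scaled to the reads counted in the listed peaks, so that each column had the same sum. Bowtie 1.3.0, MACS2 2.0, HOMER and the genome build mm9 are named in the submitters' processing notes, without their roles. Whether peaks were called on pooled or separate libraries, how duplicate reads were treated and whether cut positions were shifted for the transposase was not given in the sources used here. Per the file headers, each peak carried its position, a gene section and a distance to the transcription start site (TSS). The headers of the annotation did not all match their contents: the field headed as gene symbol held the position of the peak, and the field headed as gene ID held a symbol, while the transcript, section and distance fields held what their headers say. The symbol was taken as the gene, which 148063 peaks had and 134835 lacked, for 19109 genes. Sections called TSS lay within 999 bases of a start site. Coordinates are as deposited, in mm9, and no reference genome was used here.

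The value of 1 read was the same for every peak of a library, so whole reads could be recovered. At most 3 values in a library lay more than 0.02 reads from a whole number, and in every library at least 99.9989% of values were whole by that measure. Recovered totals ran from 798555 reads in KO Tfh214 to 1373218 in WT Tfh4. Every peak held at least 10 reads over the 6 libraries, the median peak held 14, and 90.0% held under 30. Precision was therefore set by counting. Ratios of reads between libraries carry exact binomial 95% intervals, levels carry exact Poisson intervals and shares of a library carry Wilson intervals. All these intervals cover counting error only, since PCR copies are not independent molecules and no interval covers the spread between animals.

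Each pair of libraries was compared by log2((CPM + 1)/(CPM + 1)) over peaks whose higher library held at least 20 reads, and peaks at or over 2-fold were counted in each direction. Fold values in the text are on the log2(CPM + 1) scale where given as log2, which understates the change of low peaks, and are ratios of CPM where given as fold. With 1 library per group there was no replicate, so no p-value was given for a pair, and a pair compares those libraries, not the conditions. The number of 2-fold peaks expected from counting noise was taken from 200 binomial draws, in which the share of reads of each peak followed the mean share in 20 bins of peak strength. This noise level was added after the data were examined, and it decides about no single peak, since peaks with a mean of at least 20 reads varied less between libraries than independent counts and those with 5 to 20 reads varied more.

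An additive model of genotype and population was fitted to log2(CPM + 1) with limma 3.58.1 over 8986 peaks with a mean of at least 20 reads, which left 2 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its p-values set an effect against residual spread over the populations or the genotypes, not over animals. With 2 residual degrees of freedom, the main model drew most of that spread from peaks of like level. Such peaks had nearly the same SE for the genotype effect (Slc25a37 0.1147, Pdlim5 0.1148). A p-value or SE thus says little about how alike that peak's own effect was over populations. Genotype cannot be told apart from the pool of mice or from the library preparation. The design fixed before the data were examined named limma on log2(value + 1) and an additive model only. The variance trend by level and the minimum of 20 reads on average were set after exploration had shown that calls were made with the trend and none without it, so counts without the trend stand beside the main ones. edgeR 4.0.16, with TMM factors, and DESeq2 1.42.0 were run on the recovered reads as alternatives. Their scaling takes out a shift of strong peaks between libraries. Both also assume at least the spread of independent counts, while the peaks tested varied less than that. Few calls by them were therefore likely beforehand, and their low counts are weak evidence against a difference. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

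Scaling by library totals, which the CPM carry, was the main choice. Median-of-ratios factors on the same values were 0.993, 0.989 and 0.836 for WT Tfh21, Tfh214 and Tfh4 and 1.17, 1.11 and 0.939 for the KO libraries in that order, so both scalings are given where they part.

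There were 14 gene lists, fixed before the data were examined. They were Tfh identity, Th2 and IL-4 locus, IL-4 receptor with STAT and SOCS signalling, Th1, Th17, Treg, naive and memory T cell, effector and non-Tfh, coinhibitory and TCR-induced, B cell, myeloid, cytotoxic and NK, basophil and mast cell, and widely used promoters as a scaling control. For each pair of libraries a gene's peaks were summed, members at or over 1.5-fold were counted, and the median log2 ratio was placed among 10000 random lists of the same size matched on level. That percentile describes these libraries and is no test. Lists with under 3 measured members gave no value. Over the 6 libraries, camera in limma was run on the strongest peak of each gene, as an addition.

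Genes were named by a rule fixed before the data were examined. For KO against WT in each population and for WT Tfh4 against WT Tfh21, the 10 peaks with the largest log2 ratio in each direction past the minimum and 2-fold were named, 1 per gene, and for KO against WT the direction had to hold in at least 2 of the 3 populations. Peaks chosen by size in this way have folds that are too large on average. Their intervals are not corrected for that choice and tend to exclude 1 because of it. Stat6, Il4, Il13, Il5, Gata3, Il21, Bcl6, Cxcr5, Pdcd1, Prdm1, Maf, Tbx21, Ifng, Il4ra and Socs1 were always named, as were the 2 members of each list with the largest rise and the 2 with the largest fall. Sums over both genotypes at the always-named genes were added after the values per library had been seen.

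The additive model, the pair comparison and the placing of gene lists were tested on simulated data. Reads were drawn as independent counts around means shared by all libraries, without the shift of strong peaks that the real libraries showed. The recovery and false calls below hold for that setting and may not describe the real libraries. For the genotype effect, limma recovered 32% of 200 peaks changed 1.5-fold among 8986, 80.5% of those changed 2-fold and 99% of those changed 3-fold, with 2, 4 and 14 false calls. In the simulated pair KO against WT in Tfh21, 85% of 200 peaks changed 2.5-fold, 95.5% changed 3-fold and 100% changed 4-fold passed 2-fold, together with 78, 69 and 78 unchanged peaks. In the simulated pair WT Tfh4 against WT Tfh21, all 20 lists of 20 genes changed 1.5-fold left the central 95% of random lists, as did 2 of 20 unchanged lists, among 12152 genes.

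Alternatives covered the scaling, the minimum of reads, the pseudocount, the fold threshold, the class of peak, the tool, the block and leaving out libraries. No values per sample were left unused.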

Results

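The 6 libraries held 1122701 reads in peaks for WT Tfh21, 1271755 for WT Tfh214 and 1373218 for WT Tfh4, and 1051120, 798555 and 1238585 for the KO libraries in that order. Peaks at a TSS took 31.5% of reads (Wilson 95% interval 31.5 to 31.6) in WT Tfh21, 31.0% (30.9 to 31.1) in WT Tfh214 and 27.6% (27.6 to 27.7) in WT Tfh4. In the KO libraries they took 36.4% (36.3 to 36.5), 34.9% (34.8 to 35.0) and 29.7% (29.6 to 29.8). In each population the KO library thus held more of its reads at start sites, and in each genotype Tfh4 held the least. The 8986 peaks with a mean of at least 20 reads, of which 75.9% lay at a TSS, showed the same order, from 27.2% in WT Tfh4 to 37.9% in KO Tfh21. These shares shift the median of the stronger peaks between libraries, and the shift is given with each comparison.

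**Figure D1:**
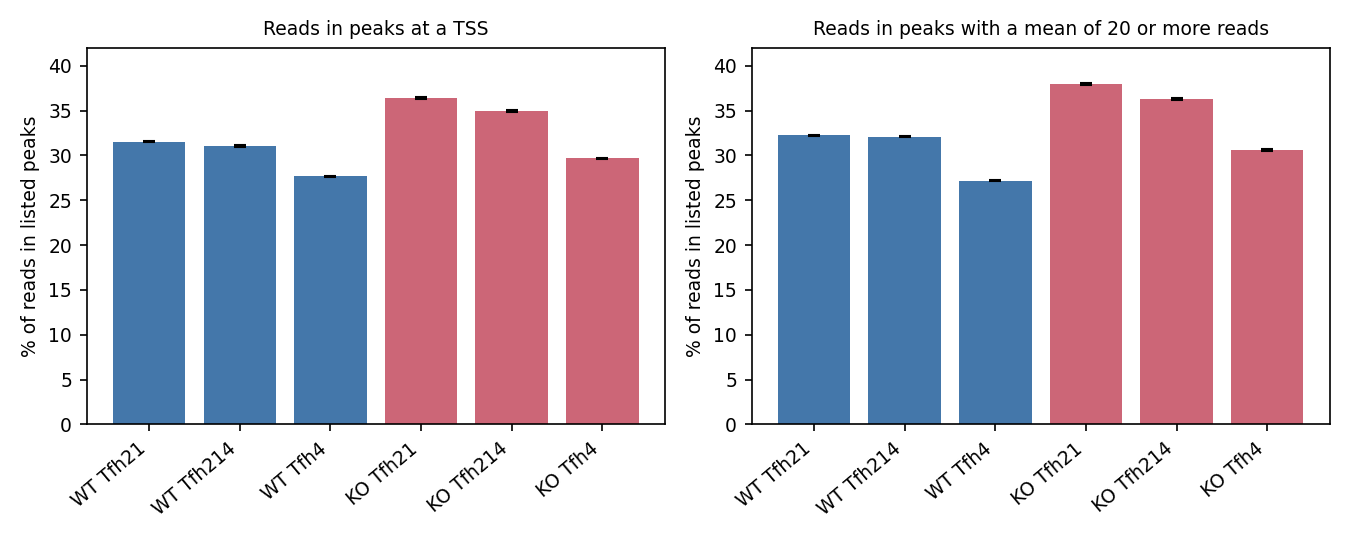
Share of each library's reads, in %, that fell in peaks at a TSS (left) and in the peaks with a mean of at least 20 reads (right). Bars stand for single libraries (WT blue, KO red) with Wilson 95% intervals, and KO lies above WT in each population, by the widest gap in Tfh21 (36.4% against 31.5% at start sites).

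At Stat6, the targeted gene and a transcription factor activated by IL-4 signalling, 6 peaks on chromosome 10 were listed. Their reads summed to 51, 69 and 58 in WT Tfh21, Tfh214 and Tfh4 and to 57, 51 and 68 in KO, that is 45.4, 54.3 and 42.2 CPM against 54.2, 63.9 and 54.9 CPM. Pooled over populations, 176 KO and 178 WT reads gave a KO to WT ratio of 1.21 (95% interval 0.974 to 1.49), and 1.06 (0.857 to 1.32) with median-of-ratios scaling. The strongest peak lay at the TSS (127078949 to 127079659) and 5 of the 6 peaks lay at or near the start of the gene. Which part of Stat6 the allele lacks was not given in the sources used here, so accessibility at these peaks checks no genotype label.

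Il4, which encodes the cytokine IL-4, had more reads in Tfh214 and Tfh4 than in Tfh21 when the genotypes were pooled. Its 2 start-site peaks (chromosome 11, 53430745 to 53430999 and 53431680 to 53432106) held 2, 12 and 10 reads in WT Tfh21, Tfh214 and Tfh4, and 2, 7 and 6 reads in KO. Within a genotype the interval excluded 1 for WT Tfh214 over WT Tfh21 (5.30-fold, 1.18 to 48.7) and not for WT Tfh4 (4.09-fold, 0.871 to 38.4), KO Tfh214 (4.61-fold, 0.877 to 45.5) or KO Tfh4 (2.55-fold, 0.455 to 25.8) over Tfh21. Pooled over genotypes, Il4 stood at 4.99-fold in Tfh214 over Tfh21 (95% interval 1.66 to 20.2) and 3.33-fold in Tfh4 over Tfh21 (1.07 to 13.7). With median-of-ratios scaling it stood at 5.20-fold (1.73 to 21) and 4.06-fold (1.31 to 16.7). KO to WT at Il4 was 0.762 (0.372 to 1.51), so a difference by genotype was not detectable with 15 and 24 reads. Il13 and Il5, its neighbours, held 42 and 22 reads over all libraries, and each of their pooled intervals included 1.

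Tbx21, which encodes T-bet, the main regulator of Th1 cells, ran the other way, at 0.586-fold in Tfh214 against Tfh21 (0.403 to 0.844) on 48 and 86 reads, and 0.611-fold (0.420 to 0.880) with median-of-ratios scaling. Among its 9 peaks, those in intron 1 at 96963602 to 96964627 and 96974055 to 96974472 on chromosome 11, chosen after their values were seen, were 10.0-fold (2.44 to 88.0) and 3.33-fold (1.3 to 10.1) higher in Tfh21 than in Tfh214. The start-site peak was not, at 1.13-fold in Tfh214 over Tfh21 (0.493 to 2.61). Maf, Cxcr5, Il21 and Pdcd1, genes of Tfh identity, were lower in Tfh4 than in Tfh21, at 0.711 (0.584 to 0.865), 0.683 (0.535 to 0.873), 0.639 (0.438 to 0.928) and 0.785 (0.623 to 0.988) of its level. Relative to the shift of all strong peaks they did not stand apart, since with median-of-ratios scaling the ratios were 0.867 (0.712 to 1.06), 0.833 (0.652 to 1.06), 0.779 (0.534 to 1.13) and 0.957 (0.760 to 1.20). Of the 15 always-named genes, 8 had a Tfh4 to Tfh21 interval that excluded 1, and 1 (Il4) kept it after that scaling; for Tfh214 against Tfh21 it was 2 (Il4 and Tbx21) under both scalings. Bcl6, the main regulator of the Tfh program, stood at 0.974 (0.749 to 1.27) and 0.953 (0.744 to 1.22) of Tfh21 in Tfh214 and Tfh4, and Il4ra at 0.957 (0.726 to 1.26) and 1.01 (0.781 to 1.31). For KO against WT, Maf alone excluded 1, at 1.20 (1.03 to 1.41), and 1.06 (0.905 to 1.24) after scaling. Gata3, Prdm1, Ifng and Socs1 gave KO to WT ratios of 1.05 (0.889 to 1.24), 1.11 (0.928 to 1.34), 1.01 (0.663 to 1.54) and 0.986 (0.813 to 1.19). By population Gata3 stood at 1.41 (1.07 to 1.88) in Tfh21, where strong peaks as a whole were higher in KO, and at 0.882 (0.644 to 1.20) and 0.905 (0.676 to 1.21) in Tfh214 and Tfh4, and the difference between populations was not tested.

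**Figure D2:**
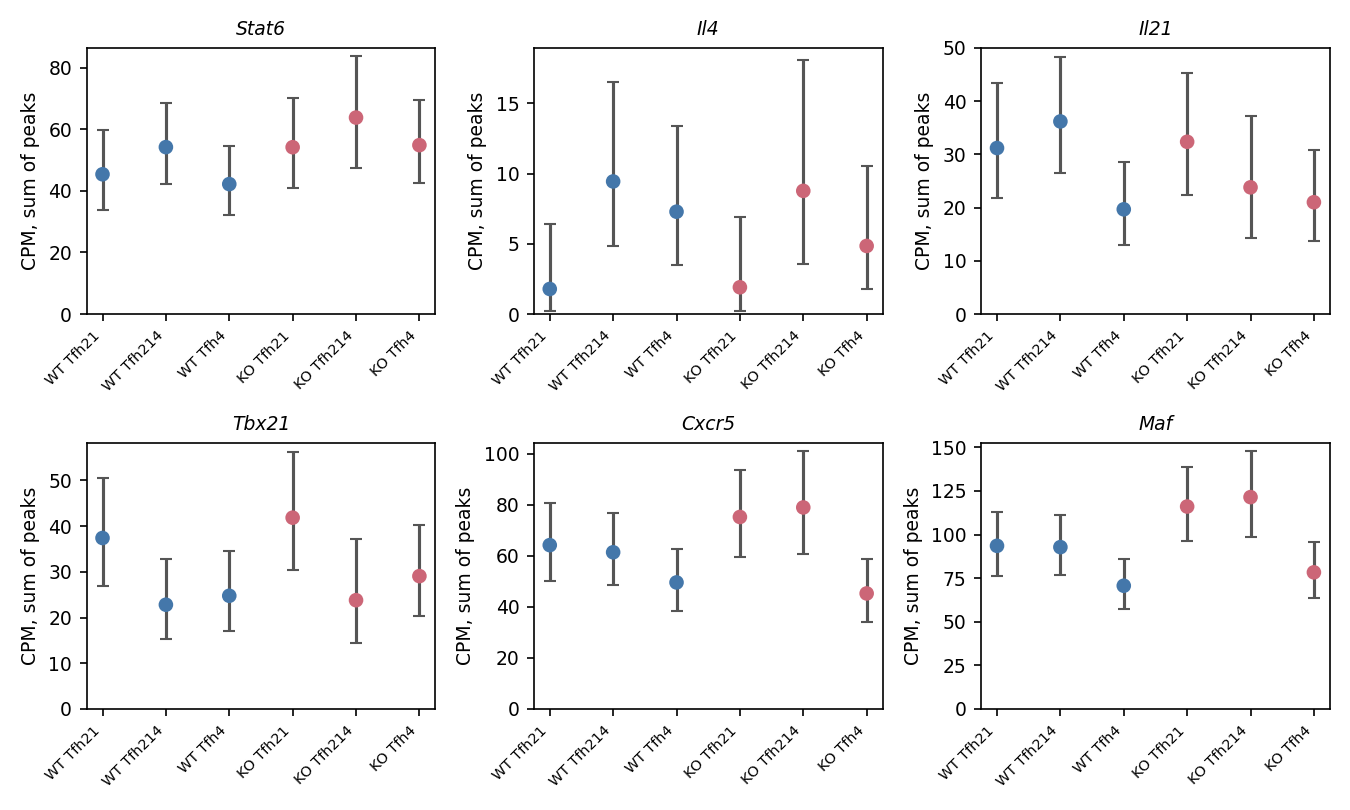
Summed CPM of all peaks assigned to 6 genes in each library (WT blue, KO red), with exact Poisson 95% intervals that cover counting error only. Il4 lies at 1.78 and 1.90 CPM in the Tfh21 libraries and at 4.84 to 9.44 CPM in the others, and Tbx21 is lowest in the Tfh214 libraries (22.8 and 23.8 CPM).

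KO Tfh21 stood above WT Tfh21 at Esr1, the estrogen receptor gene, where a peak in a 5' UTR exon (chromosome 10, 5712559 to 5713623) was 3.56-fold higher (95% interval 1.38 to 10.8; 20 and 6 reads). Peaks at Frmd4b (3.34-fold, 1.46 to 8.56), Gas2 (3.20-fold, 1.31 to 8.92) and Tspan5 (2.99-fold, 1.41 to 6.90) were higher too. Cd3d, which encodes a chain of the T cell receptor complex, was 2.88-fold higher in its first coding exon (1.35 to 6.68), and Rlf, Gramd3, Ambra1 and Trappc12 stood at 2.78- to 3.05-fold. Only 4 genes were named on the lower side, B3gnt5 at 0.243 of WT (0.0718 to 0.657), Unc45b at 0.267 (0.0893 to 0.671), Garem1 at 0.418 (0.170 to 0.938) and Hjurp at 0.464 (0.197 to 1.01). Over 10242 peaks 170 were at least 2-fold higher in KO and 8 lower, with a median log2 ratio of 0.25. The split was 44 and 21 with median-of-ratios scaling, and 3 and 82 with the trend by level removed. Counting noise with that shift gave 347 such peaks (central 95% 316 to 380), 329 higher and 18 lower, against the 178 seen.

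In Tfh214 the start site of Trappc12 (chromosome 12, 29434948 to 29435388) led the peaks higher in KO, at 3.98-fold (1.68 to 10.5; 20 and 8 reads), and it was also among those named in Tfh21. Start-site peaks of Spata2l (2.90-fold, 1.32 to 6.69), the mitochondrial chaperone gene Clpx (2.69-fold, 1.40 to 5.34), Trerf1 (2.59-fold, 1.34 to 5.16), Ncbp2 (2.5-fold, 1.22 to 5.29), Wdr6, Mir191 and Lman2l were named too, with B3gnt9 and Mid1. Lower in KO were Macrod2 at 0.217 of WT (0.0416 to 0.723; 3 and 22 reads), Inpp4b at 0.228 (0.0435 to 0.762), and Pstpip2 and 2810405F15Rik at 0.319 (0.0792 to 0.951). Rgs16, a regulator of G protein signalling, and Arhgap26 stood at 0.354 (0.119 to 0.875), and Ctnna3, Exoc2 and E230029C05Rik at 0.346 to 0.398. Of 10055 peaks 49 were higher and 70 lower, with a median log2 ratio of 0.14. The split was 10 and 115 with median-of-ratios scaling, and 34 and 8 with the trend by level removed. Counting noise gave 216 (186 to 243), 96 higher and 120 lower, against the 119 seen. Relative to the median shift 8 of the 10 named higher peaks stayed past 2-fold.

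The widest differences between the KO and WT libraries were seen in Tfh4. A peak in intron 1 of Tspan13 (chromosome 12, 36752259 to 36753040) held 20 reads in KO and 1 in WT, 22.2-fold (3.55 to 919). As for all peaks named by size, the choice inflates the fold, and the interval does not cover that choice. Pcdhgb6, a protocadherin gene, was 6.38-fold higher at its start site (2.18 to 25.4), and Sh3bgrl2 5.10-fold (1.90 to 17.2). Higher as well were Lpin1, which encodes a phosphatidate phosphatase, 4.25-fold (1.68 to 12.8), Scml4 4.07-fold (1.60 to 12.3) and the corepressor gene Nrip1 4.02-fold (1.79 to 10.2). Usp47, Tecpr1, Diaph3 and Ptpn1, a tyrosine phosphatase gene, lay between 3.19- and 3.46-fold. Lower in KO were Malrd1 at 0.164 of WT (0.0418 to 0.471), Klhdc10 at 0.202 (0.0505 to 0.594), Mllt1 and Cntn4 at 0.222 (0.0551 to 0.662) and Atg2a at 0.246 (0.0832 to 0.609), with Gnat1, Tnrc6b, Mroh2a, Psen2 and Pag1 at 0.264 to 0.333. There were 221 higher and 74 lower among 10326 peaks, with a median log2 ratio of 0.17. The split was 101 and 113 with median-of-ratios scaling, and 29 and 177 with the trend by level removed. The 295 exceeded the counting noise of 234 (208 to 259), which was the case for KO against WT in this population only. By direction that noise gave 199 higher and 34 lower, so the larger excess lay on the lower side. Of the pairs of populations, only WT Tfh4 against WT Tfh214 also exceeded its noise, and it holds the same WT Tfh4 library. WT Tfh4 against WT Tfh21 did not (183 against 260). KO Tfh4 stayed below noise against KO Tfh21 (222 against 395) and KO Tfh214 (186 against 238). A deviation of the WT Tfh4 library cannot be told apart from a difference by genotype.

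Of 9085 peaks that passed the minimum of reads in all 3 populations, 0 were at least 2-fold higher in KO in each of them and 0 lower. Peaks higher in KO were shared by Tfh21 and Tfh214 at 2 places against 0.427 for independent lists, by Tfh21 and Tfh4 at 4 against 1.48, and by Tfh214 and Tfh4 at 0 against 0.601. Peaks lower in KO were shared by Tfh21 and Tfh214 at 1 place against 0.00468, and by the other pairs at 0.

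**Figure D3:**
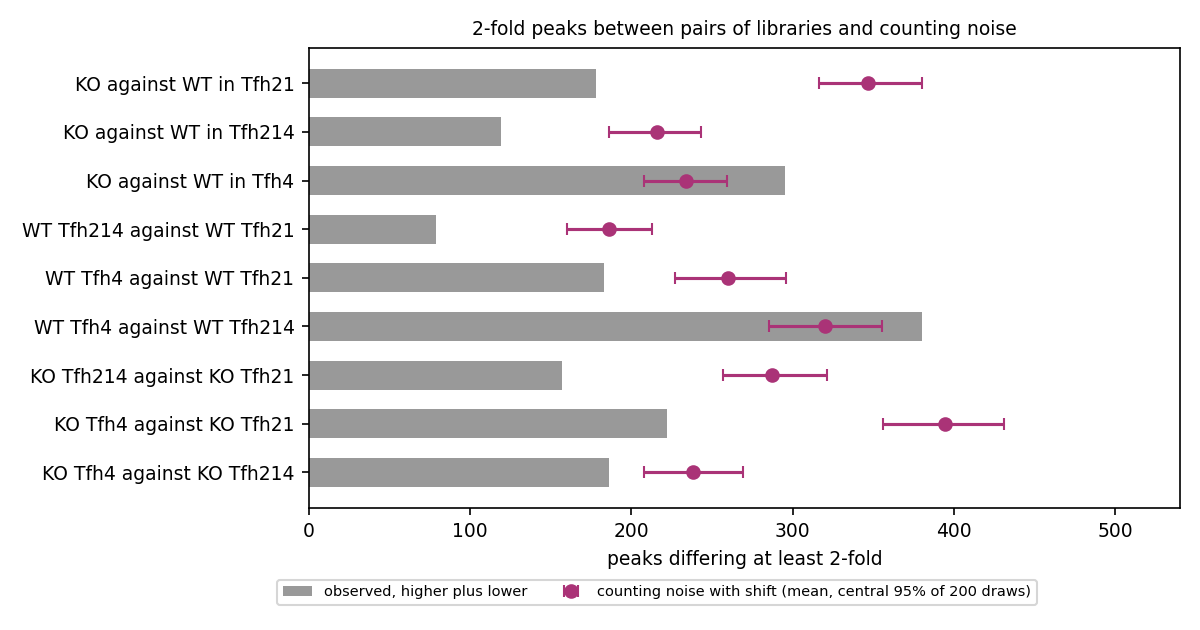
Number of peaks at least 2-fold apart (grey bars, higher plus lower) in each of the 9 pairs of libraries, beside the number from counting noise with a shift by peak strength (points, mean of 200 draws with its central 95%). KO against WT in Tfh4 (295) and WT Tfh4 against WT Tfh214 (380) lie above the noise range. Both share the WT Tfh4 library, and the other pairs lie below the range.

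Across the 3 populations, the start site of Slc25a37 (chromosome 14, 69902314 to 69903372), the mitoferrin gene of mitochondrial iron import, rose in KO. It stood at 56.1, 53.5 and 42.2 CPM in WT Tfh21, Tfh214 and Tfh4 and at 85.6, 111.5 and 71.05 CPM in KO, a log2 change of 0.79 ± 0.11 (SE; limma adjusted p = 1.41e-05, and 0.00228 with median-of-ratios scaling). An intergenic peak 57.3 kb from the nearest listed start site, that of Lpin1 (chromosome 12, 16538894 to 16539728), rose from 23.2, 23.6 and 21.85 CPM to 40.9, 55.1 and 38.75 CPM, by 0.93 ± 0.17 (adjusted p = 0.00219, and 0.0464 with that scaling). These 2 peaks, chosen after their values were seen, were the only ones called under both scalings. The genotype effect was called at 77 peaks, all higher in KO and 61 of them at a TSS, among them those of Enoph1 (log2 0.47 ± 0.09, adjusted p = 0.00296) and Zfp708 (0.73 ± 0.15, adjusted p = 0.0123), named after their values were seen, while the median of all tested peaks was 0.19 higher in KO. With median-of-ratios scaling 2 were called, with edgeR 1, and with DESeq2 or with limma without the variance trend 0 (1885 peaks had an unadjusted p under 0.05 in the main model, 218 in edgeR, 2 in DESeq2 and 1405 without the trend). Without the Tfh21 libraries 2 peaks were called, and without the Tfh214 libraries 256. The rise in KO holds for the stronger peaks only. Over all 282898 peaks the median log2 was -0.105, and 5848 of 15292 peaks with an unadjusted limma p under 0.05 were higher in KO.

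Several genes of the Th2 list were higher in the WT Tfh214 library than in the WT Tfh21 library. That list held 7 measured members, which are genes with at least 20 reads in the higher library. Il4, Il13 and Il5 were not among them in any pair. Their highest sums were 12 reads in WT Tfh214 for Il4, and 11 and 8 in WT Tfh4 for Il13 and Il5. The values of the Th2 list therefore do not cover these cytokine genes. The list had a median log2 ratio of 0.56 in WT Tfh214 over WT Tfh21, at the top of 10000 random lists. There 3 members were at least 1.5-fold higher, among them Il1rl1, the IL-33 receptor gene (log2 0.67, 26 and 14 reads), and Ccr8 (0.61, 30 and 17 reads). Gata3 stood at 0.24 and Rad50 at -0.04. The list of IL-4 receptor, STAT and SOCS genes was lower, with a median of -0.23 at percentile 0.02, with Tyk2 at -0.67. Tbx21 (-0.69) and Il18r1 (-0.84) were the 2 of 9 Th1 members that were lower, and B cell genes were higher at percentile 99.1, with Ebf1 at 1.05 (53 and 22 reads), on 3 measured members, and at 11.6 without a minimum of reads. The Th2 list fell to percentile 76.1 and the receptor list rose to 32.7 when only the highest peak of a gene was read. Over both genotypes camera placed the Th2 list slightly lower in Tfh214 (adjusted p = 0.852). Over 10386 peaks 55 were higher and 24 lower, and 4 and 98 with the trend by level removed, against 186 from counting noise (130 higher and 56 lower). In KO, Tfh214 against Tfh21 had the Th2 list at -0.33 (percentile 6.33), and lower medians for IL-4 receptor, STAT and SOCS genes (-0.20, percentile 1), Treg genes (-0.28, 1.95) and effector genes (-0.26, 2.06), with Socs3 at -0.69, Ikzf2 at -0.34 and Zeb2 at -0.42. At 1.5-fold 2 of 21 receptor genes were lower, and 0 of 6 Treg and 0 of 7 effector genes, so Ikzf2 and Zeb2 stayed short of it. With the highest peak only, the receptor list moved to percentile 80.3 and the effector list to 54.97, across the middle. Of 9947 peaks 11 were higher and 146 lower in KO Tfh214 than in KO Tfh21 (33 and 4 with the trend by level removed). Counting noise gave 287 (257 to 321), 25 higher and 262 lower, so it was lopsided the same way. Over both genotypes limma called 0 peaks between Tfh214 and Tfh21, where 345 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 as well (177 and 0 unadjusted).

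WT Tfh4 differed from WT Tfh21 at Tbc1d24, where a peak in coding exon 5 was 6.81-fold higher (2.08 to 35.3; chromosome 17, 24320087 to 24321425). Peaks at Mllt1 and Pcgf5 were 5.45-fold higher (1.62 to 28.6), at Zfp180 5.31-fold (1.84 to 21), at the presenilin gene Psen2 4.29-fold (1.45 to 17.2), at Malrd1 3.68-fold (1.49 to 10.9) and at the integrin gene Itga2 3.43-fold (1.26 to 11.7), with Gosr1, Psmf1 and Slc9a2 near 3.00-fold. Lower in Tfh4 were the start sites of Gpn1 at 0.149 of Tfh21 (0.0372 to 0.438), Abcb8 at 0.282 (0.123 to 0.595) and Klhl2 at 0.327 (0.178 to 0.576), and peaks at Jdp2 (0.238, 0.0868 to 0.570), Ttll5, Runx2, Rassf4, Zbtb4, Unc45b and Ipo11 (0.307 to 0.346). Mllt1, Psen2 and Malrd1 were also named as lower in KO Tfh4, and both comparisons share the WT Tfh4 library. Unc45b was also named as lower in KO Tfh21, and both comparisons share the WT Tfh21 library, which held 24 reads there against 6 to 10 in the others. At gene level Havcr2, a coinhibitory receptor gene, stood at a log2 ratio of 1.95 (37 and 7 reads), Ifng at -1.18 (10 and 20 reads), Tigit at -0.73 and Il21 at -0.64. The Tfh identity list had a median of -0.19 (percentile 3.11, 22 members, 2 lower), and the B cell list was higher at 0.52 (percentile 99.6, 5 members), with Ebf1 at 0.71 and Fcer2a at 0.66. Of 9929 peaks 48 were higher and 135 lower, with a median of -0.22, against 260 from counting noise (227 to 296), 37 higher and 222 lower. The observed split was 92 and 43 with median-of-ratios scaling, and 14 and 114 with the trend by level removed.

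In KO, the Tfh identity list was lower in Tfh4 than in Tfh21, with a median of -0.40 at percentile 0.01 and 5 of 23 members lower, led by Cd40lg (-0.87), the ligand gene for CD40, and P2rx7 (-0.77). The widely used promoters moved with it, at -0.39 (percentile 0.74), led by Gapdh (-0.80), and the B cell list was higher at 0.83 (percentile 99.9, 4 members), with Ebf1 at 1.14 and Fcer2a at 0.90. With the highest peak only, the Tfh identity list was at percentile 15.6 and the promoters crossed the middle, at 50.8. Of 10504 peaks 13 were higher and 209 lower, with a median of -0.31, against 395 from counting noise (356 to 431), 21 higher and 374 lower. With median-of-ratios scaling the observed split was 42 and 43, and with the trend by level removed 105 and 7.

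Against Tfh214, WT Tfh4 was lower at Tfh identity genes, with a median of -0.23 (percentile 0.96) and 5 of 23 members lower. Ascl2, a transcription factor of early Tfh cells, stood at -1.14 (13 and 28 reads) and Il21 at -0.85 (27 and 46 reads). The Th2 list was lower as well, at -0.36 (percentile 1.09), with Areg at -0.78 and Ccr8 at -0.73, but crossed the middle with the highest peak only (percentile 65.7). That result rests on the same WT Tfh214 library as the rise of the list over WT Tfh21. Havcr2 (1.53), Batf3 (1.13) and the B cell gene Fcer2a (1.17) were higher, and the B cell list stood at 0.49 (percentile 98.35, and 37.9 with genes above the median level). This pair held the most 2-fold peaks, 58 higher and 322 lower among 10573, with a median of -0.24, above the counting noise of 320 (285 to 355). That noise gave 23 higher and 297 lower, so most of the lower peaks were within reach of noise. The observed split was 112 and 118 after median-of-ratios scaling and 202 and 26 with the trend by level removed. In KO, Tfh4 was again lower than Tfh214 at Tfh identity genes (-0.26, percentile 0.99, 3 of 23 lower), led by Cxcr5 (-0.79) and P2rx7 (-0.74). The widely used promoters were lower too (-0.34, percentile 1.04), the B cell list higher (0.47, percentile 98.7), and Il7r, the IL-7 receptor gene, held 27 reads in Tfh4 and 1 in Tfh214. Of 9610 peaks 90 were higher and 96 lower, against 238 from counting noise (208 to 269), 86 higher and 152 lower. With median-of-ratios scaling the observed split was 170 and 27, and with the trend by level removed 12 and 52.

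Over both genotypes, the start site of Cpeb2 (chromosome 5, 43623828 to 43626580) fell in Tfh4, from 144.3 and 151.3 CPM in WT and KO Tfh21 to 91.0 and 99.3 CPM (limma log2 -0.63, adjusted p = 0.00029), the lowest p among 118 peaks called lower and 0 called higher against Tfh21. Against Tfh214, 178 peaks were called lower and 0 higher. The medians of all tested peaks were -0.27 and -0.23. With median-of-ratios scaling, which takes out that shift, Cpeb2 stood at -0.35 against Tfh21 (adjusted p = 0.9997), the called peaks at a median of -0.35 against Tfh21 and -0.41 against Tfh214, and limma called 0 in both contrasts. The tools edgeR and DESeq2, and limma without the variance trend, which keeps the shift, called 0 as well. At an unadjusted p under 0.05, in that order, they had 303, 157, 0 and 1759 peaks against Tfh21 and 509, 285, 2 and 1533 against Tfh214, beside 2341 and 1999 in the main model. For edgeR and DESeq2 the lack of calls adds little, since strong peaks varied less than the independent counts they assume.

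In KO against WT, most gene lists lay within the central 95% of random lists. Percentiles in Tfh21, Tfh214 and Tfh4 were 97.0, 58.8 and 77.6 for Tfh identity, 90.8, 0.56 and 41.8 for Th2 and IL-4 locus genes, and 97.8, 96.45 and 62.5 for IL-4 receptor, STAT and SOCS genes. The Th2 values leave out Il4, Il13 and Il5, which fell short of the minimum of reads. Th1 genes stood at 54.4, 50.3 and 96.7, Th17 genes at 10.7, 83.4 and 62.5, Treg genes at 49.6, 86.5 and 77.3, and naive and memory genes at 91.7, 79.2 and 93.0. Effector genes stood at 79.3, 9.06 and 44.6, coinhibitory genes at 87.8, 72.1 and 16.4, B cell genes at 13.3, 0.69 and 48.05, and the widely used promoters at 81.3, 98.8 and 38.1. Myeloid genes had enough members in Tfh214 (26.9) and Tfh4 (26.5), and the cytotoxic and NK list and the basophil and mast cell list had under 3 measured members in every pair. The Th2 list in Tfh214 was lower in KO with a median of -0.45 and 2 of 7 members lower, Il1rl1 at -0.96 (8 and 26 reads) and Rad50 at -0.63 (22 and 55 reads), while the B cell genes Ebf1 and Pax5 stood at -0.46 and -0.44 there (B cell list at percentile 56.9 without a minimum of reads). Every pair in which the Th2 list lay outside the central 95% of random lists holds the WT Tfh214 library. The others were WT Tfh214 against WT Tfh21 and WT Tfh4 against WT Tfh214. A deviation of that 1 library cannot be told apart from a difference by genotype or population. Among the receptor genes Stat5a was 0.69 higher and Jak3 -0.37 in Tfh21, and in Tfh4 Socs2 stood at -0.68 and Il21r at -0.54. Sh2d1a, which encodes the adaptor SAP, was higher in KO by 0.90 in Tfh21 and 0.59 in Tfh4, and Havcr2 by 1.47 in Tfh21 (20 and 7 reads). In all 9 pairs, 20 of 104 list medians lay outside the central 95%, where 5.2 would if list genes behaved as random genes of like level. Lists share genes and pairs share libraries, and 2 of 20 unchanged lists also lay outside in the simulated data. The distance from 20 to 5.2 is therefore no test.

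Tested over the 6 libraries with camera, none of the 10 lists with enough genes passed the threshold in any of the 4 contrasts. The B cell, myeloid, cytotoxic and NK, and basophil and mast cell lists were too small for it. The lowest adjusted p was 0.156, for the widely used promoters lower in Tfh4 than in Tfh21, which became an adjusted p of 0.827 with an estimated correlation. Among 97 list genes with a strong enough peak, limma called 4 by genotype when adjusted over the list alone (Ywhaz, Socs5, Cd69 and Pdcd1, all risen in KO) and 0 of them when adjusted over all genes. For Tfh4 against Tfh21 it called 10 adjusted over the list alone, all fallen (Ywhaz, Socs5, Maf, Btla, Eef1a1, Stat3, Foxp1, Id2, Cd200 and Tcf7), and 2 over all genes. For Tfh4 against Tfh214 it called 4 adjusted over the list alone, all fallen (Maf, Btla, Cebpa and Tbp), and 3 over all genes, and for Tfh214 against Tfh21 it called 0 by either. With median-of-ratios scaling 0 were called in any contrast.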

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

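All tests in this part were chosen after the result was seen, except the comparison of spread between dense and sparse peaks, whose outcome was set down before.

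At 5 peaks, KO stood on opposite sides of WT in Tfh214 and in Tfh4, by at least 2-fold each way. A peak in the 5' UTR exon of Gli1, an effector of hedgehog signalling (chromosome 10, 126776466 to 126777528), had log2 ratios of 1.09 in Tfh214 and -1.69 in Tfh4, and the start site of Ints2 1.07 and -1.08. Intron peaks of Atg2a (1.43 and -1.82), which serves autophagy, and Gpr107 (1.12 and -1.57) went the same way, and an intron peak of Usp53 the other way (-1.003 and 1.06). The difference between the populations was not tested, since each value rests on 2 libraries. Independent counts gave a mean of 5.78 such peaks (highest 17 in 200 draws).

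Strong peaks were higher in the KO libraries by a median log2 of 0.19 over 8986 peaks, and median-of-ratios scaling, which takes that median out of all alike, left 2 of the 77 peaks called higher in KO and moved the median log2 of the 77 from 0.49 to 0.30. The calls ended because the folds shrank by the shift, so this does not show whether a larger share of KO reads in strong peaks was their source. A share of that kind may come from the preparation of the libraries or from the cells, and genotype cannot be told apart from either with 1 pool of mice per genotype. The 13 widely used promoters were 0.17 higher (0.05 to 0.27), near the median of all strong peaks, which leaves open whether T cell genes moved on their own. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one, 77 peaks) gave as many calls and the highest other gave 0. This decides nothing, since 10 splits can never give a share under 0.1. In the other splits the shift between KO and WT also entered the residual, which left little room for calls. In most of them 1 population lay wholly in each group, so the effect rested on the pair of libraries of the remaining population. For the gene lists the real value was 0, the highest other 0, and all 10 splits gave as many.

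Strong peaks varied less between libraries than independent counts would. The chi-square per degree of freedom was 0.770 for peaks with a mean of 20 to 50 reads and 0.708 for 50 to 100 reads, where independent counts give 1, while weaker peaks with 5 to 20 reads varied more, at 1.18 (1.17 to 1.20). Removal of duplicate reads by position may account for this, since it limits dense peaks most, and the 1684 peaks with the most reads per length among those with 20 to 50 reads stood at 0.687 (0.668 to 0.709), against 0.839 (0.813 to 0.864) for the 1684 with the fewest. No biological explanation was tested.

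Of 154 peaks that parted KO from WT, 47 were higher and 107 lower in KO. The densest 20 Mb window (chromosome 12, 16538894 to 36538894, with peaks at Lpin1, Taf1b and Trappc12) held 7 of them, where shuffles gave a median of 6 and a 95th percentile of 8, so that scan was negative. A count per listed peak, added after that undecided outcome, gave 7 of 156 against 0.848 expected, reached by 11 of 1000 shuffles, so a segment that differs in sequence between the pools of mice could not be excluded. Of 3 splits of the libraries that mix the genotypes, WT Tfh21, KO Tfh214 and WT Tfh4 against the rest gave 206 such peaks with 9 in the densest window, and the others gave 78 with 4 and 86 with 5. A change in copy number of the whole segment in all mice of a pool is argued against. The log2 ratio of KO to WT background reads lay only 0.14 above that elsewhere (0.10 to 0.19). Since the SD of 129 other windows was 0.046, that difference was still large, and a change in some of the pooled mice stays open. In a segment of chromosome 5 with multi-copy genes, chosen after its values were seen, the log2 ratio of KO to WT background reads stood at -0.86 relative to that elsewhere (-1.02 to -0.70; 437 and 1068 reads), which is consistent with fewer copies there, although reads shared between copies of a repeated gene stay open.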

How the results depend on the processing

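The settings in this part include some chosen after the data were examined: the no-trend and filter settings of limma, the chromosomes left out and the scaling of sums over both genotypes. The cause of the changes below was not tested, except where a setting by its construction tests fewer or more peaks or asks for a larger or smaller fold. Pairs are given in the order KO against WT in Tfh21, Tfh214 and Tfh4, then WT Tfh214 against Tfh21, Tfh4 against Tfh21 and Tfh4 against Tfh214, then those in KO. Peaks at or over 2-fold numbered 178, 119, 295, 79, 183, 380, 157, 222 and 186. Without a minimum of reads they were 88205, 101461, 89026, 91314, 83833, 91517, 104838, 97652 and 102364, and with at least 50 reads 5, 1, 8, 0, 5, 26, 3, 1 and 3. Without a minimum the larger side turned in every pair but KO against WT in Tfh214. In Tfh21 KO against WT went from 170 higher and 8 lower to 37095 and 51110. With a pseudocount of 5 the totals were 48, 32, 83, 22, 57, 145, 50, 69 and 72, at 1.5-fold 1301, 877, 1615, 781, 1385, 1921, 909, 1753 and 1265, and at 3-fold 9, 13, 31, 11, 16, 51, 16, 9 and 20. Within 1 kb of a TSS there were 56, 55, 84, 34, 68, 118, 63, 112 and 83. Over 1 kb away there were 122, 64, 211, 45, 115, 262, 94, 110 and 103. Median-of-ratios and TMM factors each gave 65 for KO against WT in Tfh21, 230 for WT Tfh4 against Tfh214 and 85 for KO Tfh4 against Tfh21. With the trend by level removed, KO against WT gave 85 in Tfh21 and 42 in Tfh214, WT Tfh4 against Tfh214 228, and the KO pairs 37, 112 and 64. The 77 peaks of the genotype effect became 2 with median-of-ratios or TMM factors, 17 without a minimum, 193 with at least 50 reads, 40 with at least 10, 0 without the variance trend, 2 without the population block, 23 without chromosomes 5, 12 and 14, 1 with edgeR and 0 with DESeq2. Leaving libraries out gave 2 to 287: 2 without Tfh21, 256, 266 and 287 without both, the WT or the KO Tfh214 library, and 49, 51 and 56 in that order for Tfh4. The 118 peaks of Tfh4 against Tfh21 became 8 without a minimum, 308 with at least 50 reads and 77 with at least 10, and 0 with either scaling factor, without the trend, without the block, with edgeR or with DESeq2. The 178 of Tfh4 against Tfh214 became 9 without a minimum and 111 with at least 10 reads, and 0 under those same 6 settings (without the block 1083 and 1012 peaks had an unadjusted p under 0.05, with TMM factors 298 in the first contrast). Of 20 list medians outside the central 95%, 12 remained in number with peaks within 10 kb, 7 with the highest peak of each gene and 12 with genes above the median level. Lists that crossed the middle were B cell genes in KO against WT in Tfh214 (percentile 56.9) and in WT Tfh214 against Tfh21 (11.6) without a minimum, and in WT Tfh4 against Tfh214 with genes above the median level (37.9). With the highest peak only, Th2 genes in WT Tfh4 against Tfh214 (65.7), and in KO the IL-4 receptor list (80.3) and effector genes (54.97) in Tfh214 against Tfh21 and the widely used promoters in Tfh4 against Tfh21 (50.8) crossed it. Named peaks kept their direction in each of the 4 settings tried for them, which were median-of-ratios factors, TMM factors and pseudocounts of 0.5 and 5 (296 checks of a peak in a setting). That outcome was fixed in advance and shows nothing about robustness. The peaks were chosen at or over 2-fold, a pseudocount cannot turn a ratio, and the factors move it by far less than 2-fold. The authors' p thresholds and overlaps of peak sets were not run, since only 1 common list without p-values was deposited, and scaling by library totals is what the CPM carry. Depth limits these comparisons, with a median of 14 reads per peak over all 6 libraries, as does the single library per genotype and population.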

Other observations

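The share of reads on the X chromosome ran from 0.958% in WT Tfh4 to 1.38% in KO Tfh21, and that on Y from 0.0589% in WT Tfh214 to 0.0743% in KO Tfh214. Peaks at 0 reads made up 4.34% of the list in WT Tfh4 and 21.9% in KO Tfh214, the deepest and the shallowest library.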
